A study of Cellvibrio japonicus with 6 samples.

How the data were processed

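Total RNA from wild-type Cellvibrio japonicus grown on chitin was sequenced, per the labels, in exponential and in stationary phase, with 3 libraries per phase. Cells were stopped with a mix of ethanol and phenol, per the labels' protocols. The deposited values were RPKM per gene and library, that is reads scaled by gene length and by mapped reads, per the file headers. The aligner, the read counter and the genome build are not given in the sources used here. A second deposited table held the authors' RPKM means per group, which differed from the means of the replicates by at most 2.7e-05. A separate table held the authors' log2 fold changes, per the file headers of chitin against glucose in exponential phase, with no p-values. The glucose libraries belong to another series: 6 columns per library and 2 mean columns were not used. Some values in the opening lines of those columns were displayed while the files were being inspected, and they entered no computation, choice or statement.

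The direction of the authors' log2 fold changes was taken from genes at 0 in all exponential chitin libraries: all 14 held the spreadsheet error of the logarithm of 0, so positive values are higher on chitin. Of the authors' log2 values, those of 3779 genes were numbers and 33 were errors (26 and 7 of 2 kinds). The normalization behind it is not given in the sources used here. Exact values of 0 in it fell on the 2 most abundant genes, so the chitin libraries were quantile normalized as a check, chosen after the zeros were seen, to learn whether that step gives the same zeros.

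Mapped totals per library, 8408878 to 9740710, were recovered as the smallest totals at which RPKM times gene length gave whole reads. Of 3812 genes, 12 were at 0 in all libraries and 3799 gave whole reads in 100% of their values, within 0.004 of a read or a relative 1e-08. Lengths came from the gene table for 2224 of them and were inferred from the values for 1575, for which whole reads follow in part from the choice of length. On simulated data 6 of 6 totals and 99.27% of 1500 lengths were recovered. Listed genes held 97.85 to 98.39% of the mapped reads.

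Gene names were matched to the gene table of assembly ASM1922v1. Of the names in the files, 2605 were locus tags and 1207 symbols. By tag 2357 matched and by symbol 561, and 894 did not match; 1491 genes had a symbol. Of 4 gene names that carry coordinates, 3 had the same start and end in the gene table. The table gives no product names, so the 23 gene lists rest on symbols, and annotated was taken to mean having a symbol. The translation list held translation factors and no tRNA ligases. Ligases with a symbol, such as argS and leuS, were taken into the amino acid biosynthesis list, and glnS into the nitrogen assimilation list.

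Genes with a mean of at least 1 RPKM over the 6 libraries (3788) were tested on log2(RPKM + 1) with limma (3.58.1, R 4.3.3; eBayes with a trend; Benjamini-Hochberg adjustment, threshold 0.05), stationary minus exponential, with no replicate block. In a simulation of this comparison over 3788 genes with 200 changed, 96% of the 2-fold and 100% of the 4-fold changes were recovered, and 5.84% of calls were false. That simulation drew independent noise, which the libraries do not have. Lists with at least 5 tested members (22) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves on balance one way and does not compare it with other genes. Shares of summed RPKM were compared with exact permutation tests. Lists in the authors' table were set against 10000 random lists of the same size. The overlap with the phase calls was tested with Fisher's exact test for genes higher on chitin, as fixed in the design. Overlaps for genes lower on chitin were computed too, outside that design, and are given among the closing observations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

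The tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, between the phases, the 10 genes with a symbol and the 2 without one that had the largest fold change in each direction among those past the threshold with no overlap of the phases. It also took all chitin and N-acetylglucosamine list members, and up to 4 members of every other list (the 2 with the largest rise and the 2 with the largest drop past the threshold, or the 2 most abundant). It took the 10 annotated genes with the largest values in each direction in the authors' table, and the 10 most abundant genes of each phase. Alternatives covered the pseudocount, the filter, scaling, the limma options, a replicate block, each library left out and, for the authors' table, the fold threshold. Those added after the data were seen were voom on recovered reads, leaving out CJA_3895 and CJA_0290, the narrow chitin list, amino acid genes without tRNA ligases, each library left out for shares and overlaps, and the 10 most abundant genes left out of both list and sum for shares. The last was first computed in place of the fixed alternative, which leaves them out of the sum only, and this was corrected after its values were seen. No genome sequence was used, so GC content was not tested.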

Results

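RNA was sequenced from Cellvibrio japonicus, a soil bacterium known for its large set of enzymes that break down polysaccharides, while it grew on chitin in a defined medium. Wild-type cells were taken in exponential phase and in stationary phase, with 3 libraries in each group and 6 in all. The design text calls the triplicates biological. The deposited values were RPKM for 3812 genes. Mapped reads per library, recovered from the steps between the RPKM values, numbered 8981292, 8903995 and 8753149 in exponential replicates 1, 2 and 3, and 8803055, 9740710 and 8408878 in stationary replicates 1, 2 and 3. The median gene had 1146 to 1464 reads per library, and 3 reads on a gene of 1 kb corresponded to 0.308 to 0.357 RPKM. On the log2 scale the libraries correlated at 0.937 to 0.980 within exponential phase and at 0.953 to 0.991 within stationary phase. Exponential replicate 2 correlated at 0.956 with stationary replicate 2 and at 0.937 with exponential replicate 1. The series title also names glucose, and that comparison is described further on from the authors' table of fold changes.

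In the stationary libraries on chitin, ribosomal protein transcripts were lower than in the exponential ones, and a few genes that carry no symbol showed large rises. Of 53 ribosomal protein genes, 35 fell and none rose, though the number called ranged from 0 to 50 when each library was left out in turn. CJA_1971 rose from 1122 ± 191 to 11990 ± 4245 RPKM (SD, n = 3 per phase), a log2 fold change of 3.37 ± 0.27 (SE; limma adjusted p = 0.00137). CJA_0381 rose from 774 ± 121 to 4253 ± 879 RPKM (log2 fold change 2.45, limma adjusted p = 0.0012). The largest drops among genes without a symbol were in CJA_3054, from 377 ± 88.2 to 44.6 ± 5.37 RPKM (log2 fold change -3.03, limma adjusted p = 0.000612), and in CJA_1069, from 5107 ± 957 to 857 ± 192 RPKM (-2.58, limma adjusted p = 0.0012). These 4 genes stayed past the threshold without each of the 6 libraries in turn.

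Among genes with a symbol, zigA rose the most, from 124 ± 37.0 to 377 ± 28.2 RPKM (log2 fold change 1.64, limma adjusted p = 0.00831). The rule for named genes also took cbp6A (1.33), pel3B, named as a pectate lyase family member (1.33), and CJA_1345 (1.31), which carries the symbol tadA. That symbol is used both for a pilus assembly protein and for a tRNA-modifying deaminase. The remaining 6 of the 10 were copies of the large and small subunit ribosomal RNA genes, rrlA to rrlC and rrsA to rrsC, with log2 fold changes of 1.06 to 1.21. These copies are near-identical, so their separate values are uncertain. Ribosomal RNA genes together held 0.8465 to 1.116% of mapped reads in exponential and 1.535 to 3.114% in stationary libraries. A share this small can vary with how ribosomal RNA was handled before sequencing, so the rise was not read as a change in its level. The calls of these copies held in 2 to 4 of the 6 fits that each left out a library. Among genes with a symbol that fell, 9 of the 10 with the largest drops encoded ribosomal proteins, led by rpmC, which fell from 1896 ± 773 to 556 ± 94.8 RPKM (log2 fold change -1.69, limma adjusted p = 0.021). The other was uvs112 (-1.56, limma adjusted p = 0.00471).

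In all, limma called 588 of 3788 tested genes at an adjusted p under 0.05, 115 higher and 473 lower in stationary phase, and 114 of them changed at least 2-fold (26 higher, 88 lower). Fold changes are on the log2(RPKM + 1) scale. The values of the phases did not overlap for 1542 genes, or 40.7% of those tested, against 10% by chance. The count was 246 without exponential replicate 1, 58 without exponential replicate 3, 42 without stationary replicate 1 and 104 without stationary replicate 2. The balance of directions depended on scaling: 19.6% of calls were higher in stationary phase as deposited, 3.21% after rescaling to equal RPKM sums, which moved the median of all genes to -0.23, 32.5% after quantile normalization, and 48.7% after CJA_3895 and CJA_0290 were left out and the rest rescaled.

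Genes for ribosomal proteins, translation factors, ATP synthase, the respiratory chain and type II secretion were among those that fell. The ribosomal protein list had a median log2 fold change of -1.05, with 35 of 53 genes lower over all genes tested and 44 adjusted over the list alone (camera adjusted p = 2.27e-13, but adjusted p = 0.666 with an estimated correlation). Beside rpmC, rpsQ fell from 1451 ± 538 to 452 ± 78.7 RPKM. Of 13 translation factor genes, 8 fell, 9 adjusted over the list alone (camera adjusted p = 0.00126, but adjusted p = 0.666 with an estimated correlation). They included tuf (CJA_0684), which encodes elongation factor Tu, at -1.18, and infC, for a translation initiation factor, at -1.01. Of 29 ATP synthase and respiratory chain genes, 9 fell, with atpH at -1.25 and atpF at -1.15, and 18 passed adjusted over the list alone, 1 of them higher (camera adjusted p = 0.00126, but adjusted p = 0.666 with an estimated correlation). Of 15 type II secretion genes, 9 fell, 12 adjusted over the list alone, with the pseudopilin gene gspG at -0.95 and gspF at -0.65 (camera adjusted p = 0.00126, but adjusted p = 0.666 with an estimated correlation).

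Smaller drops passed the same test in 3 further lists. Of 14 fatty acid biosynthesis genes, 5 fell and 9 passed adjusted over the list alone, with accB at -0.88 and acpP, for acyl carrier protein, at -0.80 (camera adjusted p = 0.0145, but adjusted p = 0.666 with an estimated correlation). Of 36 mobile element genes, 6 fell and 13 passed adjusted over the list alone, with the transposase gene tnpC (CJA_1254) at -0.61 and the integrase gene int at -0.60 (camera adjusted p = 4.46e-05, but adjusted p = 0.666 with an estimated correlation). Transposon copies can share reads, so these values are uncertain. Of 26 type IV pilus genes, 6 fell, among them the pilin gene pilA at -0.69 and pilL at -0.61. The member that rose was tadA (CJA_1345), which is in the list by its symbol only and may encode the tRNA-modifying deaminase instead of a pilus protein. In this list 9 members passed adjusted over the list alone (camera adjusted p = 0.0209, but adjusted p = 0.666 with an estimated correlation). Without exponential replicate 1 the fatty acid list (camera adjusted p = 0.0811) and the pilus list (0.0864) no longer passed, and the pilus list was also lost without stationary replicate 1 (0.0542) or 2 (0.175). Ribosomal protein genes called fell to 23 without exponential replicate 1, 1 without exponential replicate 3, 0 without stationary replicate 1, 1 without stationary replicate 2 and 24 without stationary replicate 3; the list's median log2 fold change lay between -1.35 and -0.81 when each library was left out in turn, and was -0.67 after quantile normalization. In the other 6 lists the genes that fell were also fewer without some libraries. Without exponential replicate 3 or stationary replicate 1, 0 were called lower in any of the 6. Without stationary replicate 2 there was 1 type II secretion gene and 1 pilus gene, and 0 in the other 4. Without exponential replicate 1 there were 4 of ATP synthase and the respiratory chain, 2 of type II secretion, 1 of the pili and 0 of fatty acid synthesis and mobile elements. Without exponential replicate 2 there were 16 of ATP synthase and the respiratory chain, 2 mobile element and 2 pilus genes, and without stationary replicate 3 there were 11 pilus genes. The counts also depended on scaling, while all 7 lists stayed called by camera. Genes called lower numbered 6 for ribosomal proteins, 1 for type II secretion and 0 for the other 5 lists with median centring. With equal RPKM sums they numbered 48 for ribosomal proteins, 10 for translation factors, 23 for ATP synthase and the respiratory chain, 12 for type II secretion, 10 for fatty acid synthesis, 25 for mobile elements and 18 for pili. After quantile normalization they were 33, 7, 10, 3, 1, 0 and 4 in the same order.

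The chitinase genes chi18A and chi18C were called lower in stationary phase, though not in every fit that left out a library. The list of genes taken for chitin degradation did not pass camera's test. Of 24 genes in this list, which takes in all genes named as carbohydrate-binding proteins, 1 rose and 4 fell, and 7 passed adjusted over the list alone, 1 of them higher. Such a name does not by itself show an enzyme or an action on chitin. The chitinase gene chi18A fell from 637 ± 20.9 to 291 ± 71.2 RPKM (log2 fold change -1.15, limma adjusted p = 0.0111) and chi18C from 1038 ± 69.6 to 597 ± 155 RPKM (-0.83, limma adjusted p = 0.0287). The genes cbp33/10B (-0.90) and cbp35A (-0.39) fell as well, and cbp6A rose. Of the 6 fits that each left out a library, the call of chi18A held in 3 and that of chi18C in 2. The call of cbp35A held in 1, and that of cbp33/10B in all 6. The chitinase gene chi18D was at 1948 ± 177 and 1217 ± 359 RPKM (limma adjusted p = 0.0595), and cbp33A, of a family of lytic polysaccharide monooxygenases that cut chitin by oxidation, at 3061 ± 165 and 4043 ± 1042 RPKM (limma adjusted p = 0.243). The list as a whole had a median log2 fold change of 0.06 (camera adjusted p = 0.644). A narrower list of 9 chitinase, hexosaminidase and cbp33 genes, added after the data were seen, had 3 genes lower, 6 passing adjusted over the list alone (1 of them higher), and a median of -0.48 (camera adjusted p = 0.202, and 0.0472 without stationary replicate 3, in a range of 0.0472 to 0.365 when each library was left out). Genes called lower in the wider list numbered 2 without exponential replicate 1 and 1 without exponential replicate 3, stationary replicate 1 or stationary replicate 2. In the narrower list they numbered 1 without each of the last 3, and 5 without stationary replicate 3. In the wider list 1 rose and 7 fell with equal RPKM sums, 0 and 2 with median centring, 2 and 3 after quantile normalization and 8 and 6 with array weights. The rise of cbp6A was lost without exponential replicate 1, exponential replicate 3 or stationary replicate 1. The members of the list for use of the chitin monomer N-acetylglucosamine, too few for camera, were nagK (CJA_1160; log2 fold change -0.36, limma adjusted p = 0.133), the deaminase gene nagB (-0.34, limma adjusted p = 0.0544) and glmS, which acts in the opposite, synthetic direction (-0.21, limma adjusted p = 0.222). A further gene with a nag symbol, nag9A, was not in the list and was picked after its values were seen (-0.24, limma adjusted p = 0.146).

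**Figure D1:**
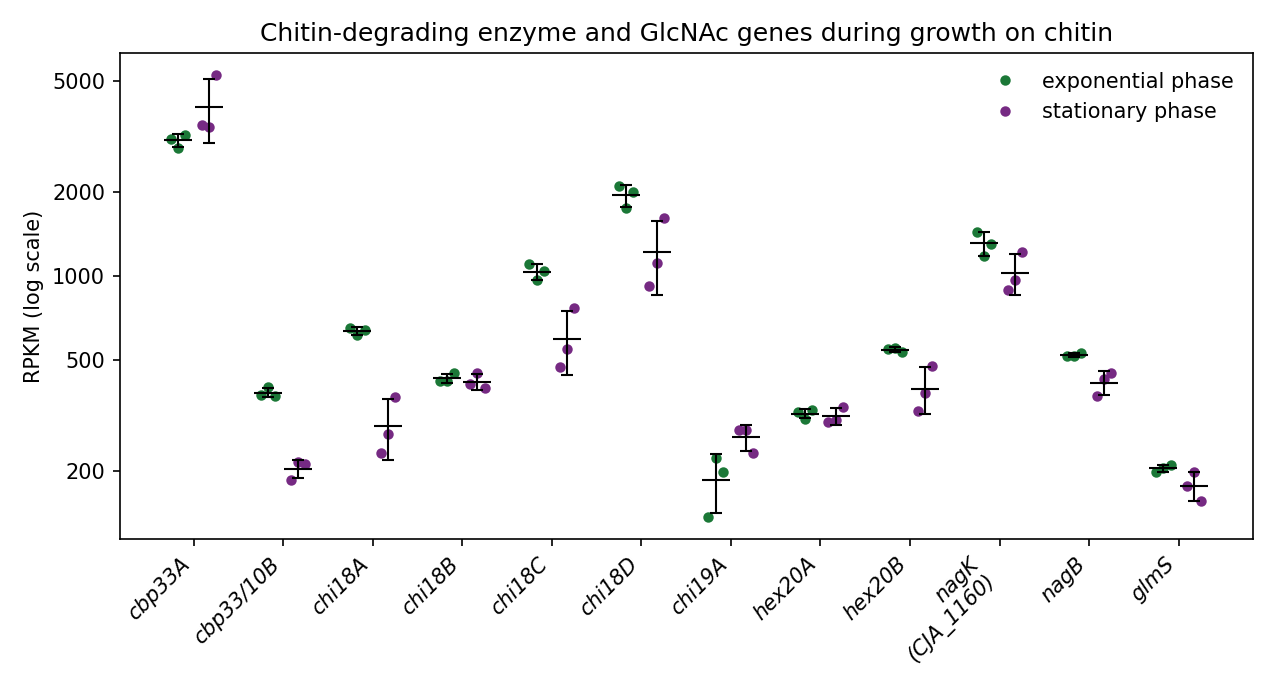
RPKM (log axis) of 9 chitin-degrading enzyme genes and 3 N-acetylglucosamine genes in the 3 exponential and 3 stationary libraries on chitin, with points for libraries, horizontal marks for means and bars for the SD. The chi18A libraries were lower in stationary phase, at 291 ± 71.2 against 637 ± 20.9 RPKM, while cbp33A was at 3061 ± 165 RPKM in exponential and 4043 ± 1042 RPKM in stationary phase.

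The other lists did not pass the camera test. Among 87 genes for enzymes acting on other polysaccharides, 3 rose and 7 fell, 10 adjusted over the list alone: pel3B at 1.33 and abf51A at 0.42 rose, and the cellulase gene cel5B at -1.31 and cel3B at -1.03 fell (camera adjusted p = 0.057). This list passed upward in some alternatives (camera adjusted p = 0.0441 with median centring, 0.00527 with array weights, 0.0129 without exponential replicate 2 and 0.00895 without stationary replicate 3). Of 93 amino acid biosynthesis genes, 2 rose, ilvY (CJA_0667) at 0.40 and ilvD at 0.35, and 11 fell, with dapF at -0.98 and trpB at -0.75. In this list 13 passed adjusted over the list alone (camera adjusted p = 0.644). The 93 include tRNA ligases. Without them 2 of 83 genes rose and 11 fell (camera adjusted p = 0.591). In cell division and peptidoglycan synthesis 5 of 31 rose, led by mraW at 0.54 and mraZ at 0.41, and 3 fell, with mreB at -0.79 and mreC at -0.53 (8 adjusted over the list alone, camera adjusted p = 0.419). With equal RPKM sums 0 of these rose and 9 fell, and with median centring none passed. Of 20 chaperone and protease genes, hspC2 rose by 0.54 and 3 fell, with groL at -0.83 and tig at -0.75 (5 adjusted over the list alone, camera adjusted p = 0.139). Nitrogen assimilation had 3 of 14 lower, with gltB at -0.89 and glnA at -0.74 (3 adjusted over the list alone, camera adjusted p = 0.609), and purine and pyrimidine synthesis 3 of 25, with carA at -0.86 and carB at -0.58 (2 adjusted over the list alone, camera adjusted p = 0.352).

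A single gene fell in each of 4 lists: fliS (CJA_1701; -0.33) of 44 for flagellum and chemotaxis (0 adjusted over the list alone, camera adjusted p = 0.292), gnd (-0.65) of 14 for glycolysis and the Entner-Doudoroff pathway (0 adjusted over the list alone, 0.51), grxC (-0.55) of 11 for oxidative stress (1 adjusted over the list alone, 0.609) and pstH (-0.55) of 11 for phosphate acquisition (1 adjusted over the list alone, 0.598). No gene passed in the 9 stationary phase and stress regulators (camera adjusted p = 0.644), where rpoS, the general stress sigma factor, was at 764 ± 0.807 and 946 ± 279 RPKM, and rmf (CJA_2157), whose product inactivates ribosomes, at 8364 ± 433 and 5598 ± 919 RPKM. Nor did any pass in iron acquisition (5 genes, 0.302; bfr -0.01, fur 0.03), TonB (5 genes, 0.352; exbB1 0.47, tonB-2 0.30) or the TCA cycle (8 genes, 0.208; sucC -0.58, sucD -0.57), although 2 TCA genes passed adjusted over the list alone, against 0 in the other 3. The direction of the camera test and the sign of the median differed for flagellum and chemotaxis (median -0.04, test upward) and phosphate acquisition (median -0.07, test upward). In 3 lists with a median above 0 the mean lay below 0: cell division (-0.01), chitin degradation (-0.01) and stress regulators (-0.01). Over these 14 lists, the chitin list apart, 11 genes rose and 34 fell among 376. The numbers were 3 and 12 without exponential replicate 1, 7 and 44 without exponential replicate 2, 0 and 2 without exponential replicate 3 or stationary replicate 1, 1 and 5 without stationary replicate 2, and 9 and 39 without stationary replicate 3. They were 0 and 6 with median centring, 2 and 120 with equal RPKM sums, 16 and 14 after quantile normalization, and 39 and 24 with equal sums after CJA_3895 and CJA_0290 were left out.

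Of the 10 most abundant genes of exponential phase, 4 fell in stationary phase and 6 did not pass the test, the leading pair among the latter. The tmRNA gene ssrA (CJA_3895), whose RNA rescues stalled ribosomes, lay at chromosome positions 1443870 to 1444223 (assembly ASM1922v1). It was at 91990 ± 5710 RPKM in exponential and 226700 ± 21740 RPKM in stationary phase, higher in 3 of 3 libraries (log2 fold change 1.30, limma adjusted p = 0.645 with a variance trend over abundance). Its adjusted p was 0.00193 with limma without that trend, in a range of 0.00193 to 0.867 over the alternatives apart from quantile normalization. That step leaves no fold change for a gene with the same rank in every library, so it tests nothing for CJA_3895 and CJA_0290. CJA_0290 was at 21710 ± 5006 and 106800 ± 26620 RPKM (log2 fold change 2.29, limma adjusted p = 0.0726, 0.00483 without the trend, and 0.00459 to 0.287 over the same alternatives). CJA_2729 fell from 9425 ± 1460 to 2500 ± 1129 RPKM (-1.99, limma adjusted p = 0.0152), CJA_1919 from 2918 ± 237 to 1298 ± 291 RPKM (-1.19, limma adjusted p = 0.0111) and CJA_0916 from 3402 ± 404 to 1951 ± 584 RPKM (-0.83, limma adjusted p = 0.0456). CJA_1157 (log2 fold change -0.55), CJA_2390 (-0.16) and CJA_1659 (0.54) did not pass.

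Neighbouring genes moved together at 2 places, both chosen after their values were seen. All 18 genes from CJA_3040 to CJA_3057, at chromosome positions 3608463 to 3631147 (assembly ASM1922v1), fell, with a median log2 fold change of -1.58 (range -3.03 to -1.04). Their means were 64.9 to 445 RPKM in exponential and 27.2 to 209 RPKM in stationary phase. CJA_3053 fell from 365 ± 73.5 to 61.3 ± 4.01 RPKM (limma adjusted p = 0.000612). The next locus tag, CJA_3058, fell as well (log2 fold change -1.23, limma adjusted p = 0.00671). It has no position in the gene table and was counted neither in the run nor among its neighbours. CJA_1304, CJA_1305 and CJA_1306 rose by 2.06, 2.17 and 2.42 on the log2 scale, CJA_1306 from 68.0 ± 1.12 to 373 ± 71.9 RPKM (limma adjusted p = 0.000612). All 3 stayed past the threshold without each library in turn. Of the 18 genes that fell, 15 stayed called without exponential replicate 3, 8 without stationary replicate 1 and 15 without stationary replicate 2.

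**Figure D2:**
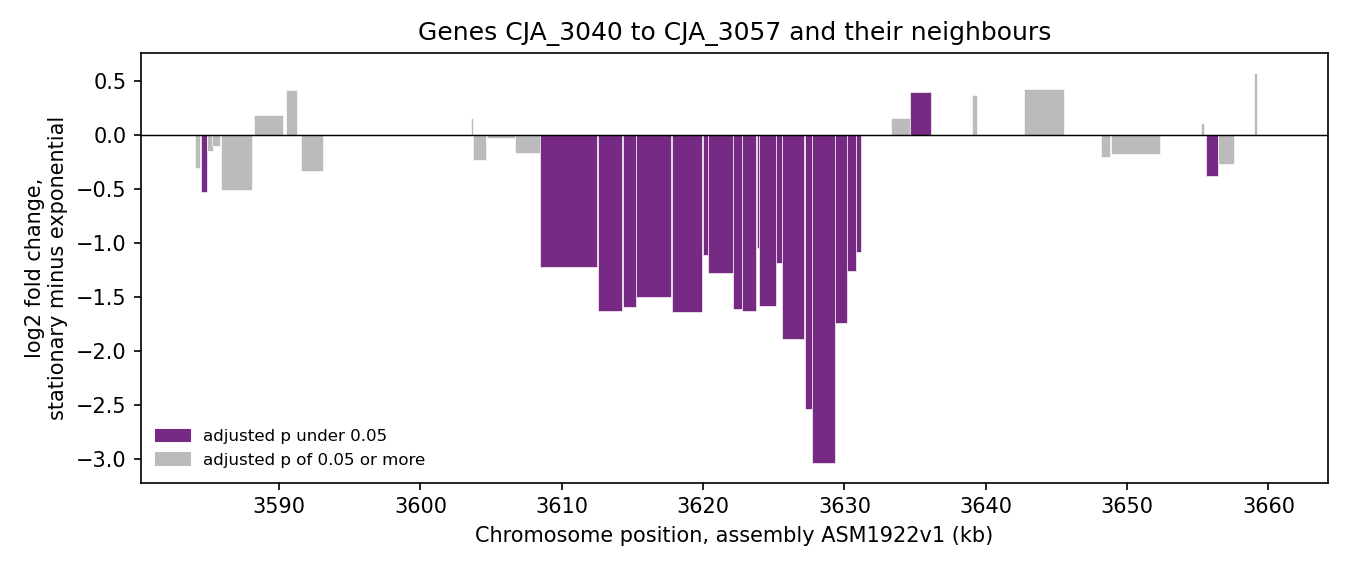
Log2 fold change in stationary minus exponential phase (vertical axis) of CJA_3040 to CJA_3057 and neighbouring genes, drawn as bars at their chromosome positions in kb and coloured by whether the limma adjusted p was under 0.05. The 18 genes lie between -3.03 and -1.04, and the 20 genes on either side have a median of 0.00.

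Ribosomal protein genes took 5.95 ± 1.97% of summed RPKM in exponential and 2.35 ± 0.202% in stationary phase (n = 3 each, exact two-sided permutation p = 0.1). For the chitin list the shares were 1.13 ± 0.0106% and 0.947 ± 0.126% (exact permutation p = 0.1), and for the 10 most abundant genes 15.0 ± 0.966% and 31.6 ± 2.59% (exact permutation p = 0.1). The rise of these 10 genes lay in CJA_3895 and CJA_0290. CJA_3895 took 8.69 to 9.67% of summed RPKM in exponential and 18.48 to 21.09% in stationary libraries, and CJA_0290 1.80 to 2.68% and 7.16 to 11.4%. The lower chitin share depended on the denominator. With the 10 most abundant genes left out of the sum the difference between the phases turned from -0.182 to 0.0599 percentage points (exact permutation p = 1). It was -0.0914 when they, cbp33A among them, were left out of the list as well (exact permutation p = 0.2). In the narrower chitin list the difference was -0.183 percentage points (exact permutation p = 0.1) and did not reverse. There it was -0.0233 with the 10 most abundant genes left out of the sum, with stationary libraries (0.840 to 1.213%) on both sides of the exponential ones (0.958 to 1.025%). With them left out of that list too it was -0.175 (exact permutation p = 0.1). The smallest p that 3 against 3 can give is 0.1.

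Growth on chitin rather than glucose in exponential phase was marked, in the authors' deposited table, by higher levels of genes for chitin breakdown. In the authors' deposited table cbp33A was 105-fold, chi18C 35.1-fold, hex20B 17.7-fold and chi18A 15.5-fold higher on chitin, chi18D was at a log2 fold change of 6.66, and nagK (CJA_1160) 23.2-fold and nagB 9.67-fold higher, while glmS was at a log2 fold change of -0.31. The other annotated genes with the largest values in the authors' deposited table were phoH (28.1-fold higher), gluP (23.5), rmf (CJA_2157; 22.0), narB, for a nitrate reductase (19.8), and cyoE, for haem O synthesis (16.3). At the other end, the authors' deposited table held cobP (13.9-fold lower), cobD (11.6) and cobQ (10.8) of cobalamin synthesis, bioF (11.7) and bioC (11.3) of biotin synthesis, phnA (11.6), fmt (10.3) and the glycosyltransferase gene gt2J (10.8). The glycosyltransferase genes gt4E and gt9A were at log2 fold changes of -3.59 and -3.32 in the authors' deposited table. The authors' deposited table gave 327 genes at least 4-fold higher and 356 at least 4-fold lower on chitin among 3779 with a number. It gives no errors or p-values.

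Set against 10000 random lists matched on mean chitin RPKM, 17 of the 23 lists had a median in the authors' deposited table outside the central 95%. Lists above that range in the authors' deposited table were chitin degradation (median log2 fold change 2.12, 13 of 24 at least 4-fold higher and 0 lower), N-acetylglucosamine use (3.27, without nag9A), TonB (2.02), other polysaccharide-degrading enzymes (1.25), mobile elements (1.05) and flagellum and chemotaxis (0.97). The narrower chitin list, added after the data were seen, had a median of 3.95 in the authors' deposited table and lay above its range as well. Lists below it in the authors' deposited table were cell division (-1.65), fatty acid biosynthesis (-1.60), translation factors (-1.43), type II secretion (-1.32), glycolysis (-1.29), amino acid biosynthesis (-1.23), purine and pyrimidine synthesis (-1.20), ribosomal proteins (-0.82), oxidative stress (-0.81), ATP synthase and respiratory chain (-0.75) and chaperones (-0.60). Inside it in the authors' deposited table were the TCA cycle (0.02), iron (-0.03), nitrogen (-0.47), phosphate (0.72), stress regulators (0.31) and type IV pili (0.34). These percentiles describe the lists and are no test across replicates. The matching used the chitin libraries, whose exponential values also enter the fold changes, so the range of the random lists moved with abundance. The median of the random lists was 0.793 for ribosomal proteins and -0.683 for mobile elements. A list outside its range is thus high or low for its abundance on chitin.

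**Figure D3:**
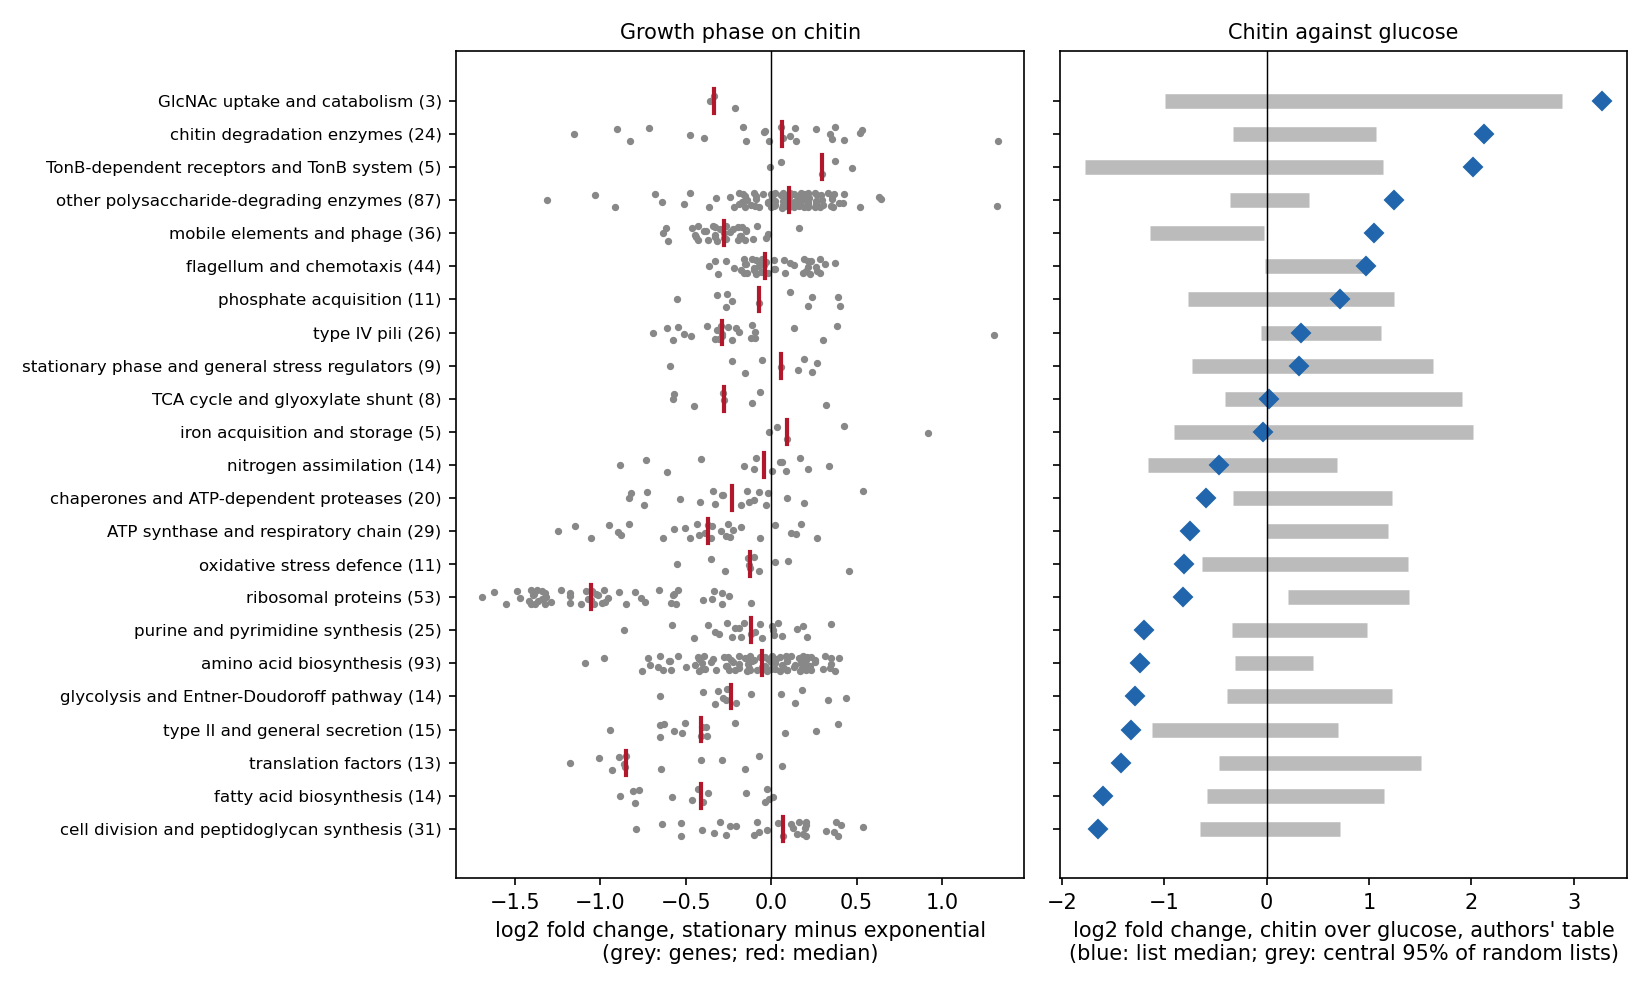
Left, log2 fold changes between the growth phases on chitin for the genes of the 23 lists (grey points) with the median (red line). Right, list medians of log2 fold changes on chitin over glucose in the authors' deposited table (diamonds) with the central 95% of random lists (grey bars). The ribosomal protein medians were -1.05 on the left and -0.82 on the right, and the chitin degradation medians 0.06 and 2.12.

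The scale of the authors' fold changes carries a limit. Exactly 2 genes of the authors' deposited table stood at 0, and they were CJA_3895 and CJA_0290, which ranked 1 and 2 by RPKM in all 6 chitin libraries. The mean over all genes of the authors' deposited table was 0.00003. When the 6 chitin libraries were quantile normalized here, the phase ratios of these genes also became 0, from log2 values of 1.30 for CJA_3895 and 2.30 for CJA_0290, and the mean over genes moved from -0.080 to -0.001. A further gene, CJA_3199, also reached 0 in that step, and no gene had a phase ratio of 0 as deposited. The values of 0 were therefore not read as unchanged levels, and fold changes of the authors' deposited table were read relative to its other genes, not as ratios of RPKM.

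Genes higher on chitin in the authors' deposited table were found more often than independent lists would give among genes that rose in stationary phase. Of the 327 genes at least 4-fold higher, 23 were called higher in stationary phase against 9.95 for independent lists (Fisher's exact test, odds ratio 2.76, p = 0.000117), CJA_1971 (11.2-fold higher on chitin in the authors' deposited table) and CJA_0381 (36.9-fold) among them. Another 34 were called lower in stationary phase against 40.9 (Fisher's exact test, odds ratio 0.796, p = 0.256). This second overlap turned above its value for independent lists when a library was left out: 22 against 17.8 without exponential replicate 1, 14 against 3.72 without exponential replicate 3, 10 against 2.6 without stationary replicate 1, 16 against 6.23 without stationary replicate 2 and 55 against 41.3 without stationary replicate 3. The other overlap was 10 against 3.46, 5 against 1.3, 4 against 1.04 and 8 against 2.77 without exponential replicate 1, exponential replicate 3, stationary replicate 1 and stationary replicate 2. Both comparisons use the exponential chitin libraries. In 100 simulations of unchanged genes sharing those libraries the overlap was 0 in both directions, but on average only 0.14 simulated genes reached 4-fold, so this value decides nothing about the overlaps. The covariance of the fold changes across genes was 0.108 against -0.0154 simulated, a difference of 0.123, and r was 0.176 against -0.499; genes are not independent replicates. The 3 shared libraries were too few to split with 2 in each part. In the simulation sharing them gave a negative covariance, opposite in sign to the observed one, and the scale of the authors' deposited table remains a limit.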

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

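Alternatives chosen after the data were seen were voom on recovered reads, leaving out CJA_3895 and CJA_0290, the narrow chitin list, amino acid genes without tRNA ligases, leaving out libraries for shares and overlaps, and leaving the 10 most abundant genes out of both list and sum for shares. Against 588 genes called between the phases (115 higher, 473 lower; 114 at 2-fold or more), median centring gave 117 (26 higher, 91 lower; 58), equal RPKM sums 1214 (39, 1175; 187), and the same without ribosomal and transfer RNA genes 1206 (36, 1170; 183). Quantile normalization gave 434 (141, 293; 70) and array weights 2058 (880, 1178; 139), with exponential replicate 3 weighted at 37.5 and the others at 0.228 to 1.29. Without CJA_3895 and CJA_0290 there were 647 (315 higher, 332 lower). Other pseudocounts, filters and variance options gave 565 to 599, and voom 619. Leaving out each library in turn gave 42 to 571 genes, 12 to 93 higher and 30 to 478 lower, and 29 to 161 at 2-fold or more. The cause was not tested.

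The replicate block gave 46 genes (15 higher, 31 lower; 40 at 2-fold or more). Residuals of libraries with the same number correlated at -0.585, 0.453 and -0.113. With 3 libraries per phase the residuals within a phase are tied to each other, as for exponential replicates 1 and 2 (-0.912). These values therefore cannot decide whether the numbers pair the libraries. The labels do not say that they do, and whether a call lost under the block is a weaker effect stays open. Not every library correlated best with its own number.

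Of the 7 lists called, 0 passed with an estimated correlation and 2 with fry (mobile elements and type II secretion; smallest adjusted p 0.0276). Leaving out each library gave 5 to 10 lists. No list or named gene called between the phases changed sign in the alternatives run, while some uncalled ones did. Of lists not called, other polysaccharides passed upward with the block (camera adjusted p 0.0407), without CJA_3895 and CJA_0290 (0.0465) and in 4 more alternatives. Chaperones passed downward with array weights (camera adjusted p 0.00567), without exponential replicate 2 (0.0465) and without stationary replicate 3 (0.00641), and the TCA cycle without exponential replicate 2 (0.0308). Of 89 named genes called, 18 stayed called without each library, 71 were lost without stationary replicate 1, 66 under the block and 50 with median centring. The chitin share difference of -0.182 percentage points reversed to 0.0599 with the 10 most abundant genes left out of the sum (exact permutation p = 1), and was -0.0914 with them left out of the list too. For the narrower chitin list it was -0.0233 and -0.175, the former with stationary libraries on both sides of the exponential ones. On chitin, 999 genes were 2-fold and 63 were 10-fold higher, and 1005 and 29 lower, in the authors' deposited table. The authors' p-value alternative was not run, since their table holds none. The overlap of genes higher on chitin with genes lower in stationary phase ranged from 10 to 55 when each library was left out. It turned above the number for independent lists in the 5 cases other than exponential replicate 2, with Fisher's exact p of 7.72e-06 at 14 genes, 0.000128 at 10, 0.000314 at 16, 0.0231 at 55 and 0.306 at 22. The cause was not tested. Depth was 8408878 to 9740710 reads, so genes near 0.357 RPKM rest on about 3 reads.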

Other observations

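Tests chosen only after the result was seen were those on the abundant RNAs, library depth and growth phase for the ribosomal genes, on sampling points and counting noise for the spread within phases, on the flanks and on shuffles for the gene run, on chromosome position for the phase comparison, and on other splits. The length and chromosome position tests were rerun with more genes covered after a value had been seen, the counting noise test replaced one on the spread between libraries, and the depth test replaced thinning to equal totals, which moved nothing.

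Picked after their values were seen, coxB (CJA_0865) was 15.2-fold and ctaD (CJA_0866) 12.9-fold higher on chitin in the authors' deposited table. Both encode cytochrome oxidase subunits. Neither is in the ATP synthase and respiratory chain list, so its median of -0.75 there does not cover them. Genes lower on chitin, outside the fixed design, overlapped with genes lower in stationary phase in 60 cases against 44.6 for independent lists (Fisher's exact p = 0.0115) and with genes higher in stationary phase in 3 against 10.8 (p = 0.00841). Without exponential replicate 3 the former overlap was 0 against 4.05, without exponential replicate 1 14 against 19.4, and without stationary replicates 1 and 2 it was 0 against 2.83 and 1 against 6.78. Without exponential replicate 2 it was 68 against 40.7 (Fisher's exact p = 9.77e-06) and without stationary replicate 3 it was 53 against 44.9 (Fisher's exact p = 0.18). By Fisher's exact test the latter was 2 against 3.77 (p = 0.581), 1 against 1.41 (p = 1), 1 against 1.13 (p = 1) and 1 against 3.01 (p = 0.359) without exponential replicates 1 and 3 and stationary replicates 1 and 2. Without exponential replicate 2 it was 2 against 7.44 (Fisher's exact p = 0.0306) and without stationary replicate 3 it was 1 against 8.76 (Fisher's exact p = 0.00181). CJA_0290 was fitted by a length of 96 and the gene table has the small RNA gene ssrS at 371439 to 371615; whether they are the same RNA was not settled.

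Ribosomal protein genes were lower in stationary phase. A larger share of reads in CJA_3895 and CJA_0290 is argued against as the whole cause, since the list's median log2 fold change was -0.95 without them. Library depth is argued against too: the shallowest and the deepest library were both stationary, and the lowest exponential list median exceeded the higher of theirs by 0.37. Growth phase stays open: the library medians separated the phases with an exact permutation p of 0.1, the smallest possible. Sampling at different points within a phase also stays open, since exponential replicate 2, at a median of 9.45 on the log2 scale, lay closer to the stationary libraries (8.74 to 9.08) than exponential replicate 1 did (10.55).

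Libraries of one phase differed along a common axis. Exponential replicate 2 minus replicate 1 correlated across genes at r = 0.618 with the mean of stationary replicates 1 and 2 minus exponential replicate 3, so sampling at different points of growth is a candidate explanation, and other handling differences stay open too. Gene length is argued against (Spearman's rho 0.048 over genes, which are not independent). Counting noise, which is independent between libraries, is argued against as the whole cause: stationary replicate 3 minus replicates 1 and 2 correlated at r = 0.562 with exponential replicate 3 minus replicate 2, which shares no library with it. Pairs of libraries of one phase differed with an SD of 0.130 (stationary replicates 1 and 2) to 0.456 (exponential replicates 1 and 2) over genes with at least 1000 reads. 

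The 18 neighbouring genes from CJA_3040 to CJA_3057 may respond to growth phase as a unit, as a hypothesis. A trend over the wider chromosome is argued against, since the 20 genes on either side had a median log2 fold change of 0.00. A single library is argued against, since the highest median without each library was -1.40. Chance placement of independent calls is argued against, since no run as long arose in 10000 shuffles of gene order (permutation p = 1e-04, the smallest they can give), the longest being of 5 genes. The shuffles treat neighbouring genes as independent, which genes transcribed together are not, and the run was picked after it was seen. They therefore cannot tell this run from any other set of neighbours transcribed together. Position-linked effects of another kind stay open.

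Fold changes may depend on distance from the replication origin, with dnaA as its marker, as a further hypothesis. In the authors' deposited table Spearman's rho of log2 fold change with distance from dnaA was 0.185 (rotation p = 0.0278), and for the phase comparison 0.258 (rotation p = 0.0211), over 3131 genes. Without ribosomal protein genes rho was 0.182 and 0.256. Gene dosage during growth is consistent with both values, but DNA was not measured, and functional placement of growth genes near the origin would give the same trend.

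The 6 libraries can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. The real split called 588 genes and the highest other 107 (exponential replicates 1 and 3 with stationary replicate 3), and at 2-fold or more 114 against 30; in each case the real split was the 1 that reached its value. For gene lists the real split called 7 and the highest other 10, and 5 of the 10 splits, the real one included, reached 7 or more.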
